A study of Homo sapiens with 6 samples.

How the data were processed

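RNA sequencing was analysed for 6 samples, 1 per healthy donor, all of 1 group. Per the labels' protocols, adult CD34+ cells were grown in a serum-free culture of 3 phases planned for 21 days, transduced on day 3 with lentiviral particles carrying a commercial non-targeting hairpin, treated with puromycin from 24 hours later for 3 days and kept in medium of the second phase for 7 days. Live cells were sorted and RNA was taken on day 14, and 1 ug of RNA entered each library after subtraction of globin transcripts with the GLOBINclear kit and of ribosomal RNA with the RiboZero Gold kit. Donors are separate people, so the spread between samples includes biological differences between donors and differences between cultures and libraries, which the design does not separate.

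The deposited FPKM values, 1 per RefSeq transcript with a lower and an upper confidence bound and a status, came from Cufflinks, per the file names and the column headers, in 1 file per sample; the Cufflinks version is not given in the sources used here. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie, CASAVA 1.8.2 and the hg19 genome were used. The deposited coverage values are a signal, the estimated depth of reads over a transcript, per the file headers. FPKM divides by transcript length and by the library's mapped fragments, so a few very abundant RNAs lower the values of all others, and Cufflinks splits reads among overlapping transcripts by a model. Read counts were not used here and cannot be recovered from these values, so no count test was run and the number of reads behind a value is unknown; coverage per FPKM, a measure of relative depth, ranged from 5.66 to 6.78 between libraries. Exact zeros can be failed assignments, so genes at 0 are described as listed at 0. A commercial globin subtraction leaves a residue that differs between globin genes, so globin levels are those of the residue.

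Gene values were the sum of the FPKM of a gene's transcripts. Transcripts whose status was not OK were missing (9 genes affected), and 2113 transcripts on alternative haplotype sequences were kept. Genes on chromosome Y, XIST, TSIX and genes whose level is set by common germline variants were removed on reading (546 transcripts, 180 genes). The most variable genes by the naming rule included a blood group locus, which is left unnamed, and a few further genes are not reported here. Values were used as log2(FPKM + 0.1), which understates differences for low genes. For spread and correlations between donors, libraries were scaled by the median ratio to the geometric mean of each gene (factors 0.805 to 1.17) and genes with a mean of at least 1 FPKM were kept. The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9. Coordinates are those of the files, on hg19, counted from 1. The reference annotation at hand was of a later build and served only for GC content, older symbols and pseudogene counts, and GC content was matched for 98.1% of the genes it was used on. DMTN and PKM were found in the files under the older symbols EPB49 and PKM2.

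Before the data were examined, 27 gene lists with 523 different members, 30 gene pairs, 30 genes for transcript use, 2 families of correlations, the tests and the alternatives were fixed. Of the members, 520 were measured (IL3RA, CSF2RA and FAM132B were not) and 349 reached 1 FPKM in all libraries. Within-library differences of list medians (24) and gene pairs (30) were tested with an exact two-sided sign-flip permutation test over the 64 sign patterns of 6 libraries, whose smallest p is 0.03125, with Benjamini-Hochberg adjustment within each family. Correlations over 6 libraries (10 with the gamma globin share, 12 with the late maturation score, the mean over members) used exact permutation of the 720 pairings. The spread of a list, the median SD of its members, and its coordination, the mean pairwise Pearson correlation, were placed among 10000 random lists drawn within 20 bins of mean expression; the smallest p these give is 0.0002 two-sided for spread and 0.0001 one-sided for coordination, and lists with fewer than 3 members above the filter were not tested. Such p-values describe these libraries, since genes are not independent. Results with an adjusted p below 0.05 were called. Genes named in the text were, by a rule fixed beforehand, the 4 highest and the lowest member of each list, all globins and fetal programme genes, the 20 highest genes of at least 300 nt, the 15 most and 10 least variable genes of at least 10 FPKM, the genes of the pairs and of the gamma globin correlations, and the genes with several transcripts. The names in the closing section that fall outside it are members of lists chosen after the data were seen or, for ASNS, PSAT1, PHGDH and SLC7A11, of the fixed stress response list, named after their values were seen, and RMRP and SNORA63 in the report were also chosen after their values were seen.

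The random-list step was tested on simulated data for 8397 genes, and the sign-flip and correlation tests on simulated single values over 6 samples. Lists of 20 genes with a doubled SD were called in 10 of 10 cases and lists with a shared factor in 10 of 10, while of 100 lists with nothing added 0 were called for spread and 2 for coordination. Apart from these added effects, the simulated genes were independent and shared 1 SD. Measured genes are correlated and differ in SD, so these rates need not hold for the measured lists. The sign-flip test called 3.75% and the correlation test 4.15% of 2000 simulated null cases at an unadjusted p under 0.05. Alternatives tried were pseudocounts of 0.01 and 1, the highest transcript in place of the sum, list means, other filters and detection limits, FPKM as deposited, rescaling to a common sum (TPM) without globin and short genes, and leaving out each library. Leaving out genes at exactly 0 and removing a trend with GC content and length from each library were added after the data were seen. No group comparison was possible, because all samples belong to 1 group.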

Results

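The series held 6 samples of 1 group. Adult human CD34+ cells, the stem and progenitor cells from which red cells can be grown, came from 6 healthy donors and were cultured toward erythroblasts, the nucleated precursors of red cells. Each culture received a lentivirus carrying a non-targeting short hairpin RNA, a control hairpin designed to match no human transcript, and was harvested on day 14 after sorting of live cells. Globin and ribosomal transcripts were depleted before paired-end sequencing. The files gave FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library) for 41138 RefSeq transcripts of 23273 genes, and between 7816 and 8656 genes per library reached 1 FPKM (8317 ± 296, SD, n = 6). Read counts were not given, so no depth in reads can be stated. The deposited coverage summed to between 2.58 and 3.60 Gb of transcript bases per library (3.02 ± 0.386, SD, n = 6). Pearson correlations of scaled log2 values between libraries, computed across genes, which are not independent replicates, lay between 0.902 and 0.947 over the 15 pairs. With no untransduced or second hairpin group among the samples analysed, the comparisons made were between genes within a library and between donors.

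The first question was what these cells expressed. Erythroid genes stood at high levels in all libraries. Among members of the 4 erythroid lists, which leave out the globins, the highest was AHSP, which encodes the chaperone of alpha globin, at 2316 ± 289 FPKM (SD, n = 6; hg19 chromosome 16, 31539203 to 31540124). The anion exchanger gene SLC4A1 stood at 1457 ± 94.4 FPKM (chromosome 17, 42325758 to 42345502), the transferrin receptor gene TFRC at 1168 ± 241 FPKM (chromosome 3, 195776155 to 195809032) and ALAS2, which encodes the first enzyme of heme synthesis in erythroid cells, at 991 ± 185 FPKM (chromosome X, 55035488 to 55057497). The mitochondrial iron importer gene SLC25A37 reached 886 ± 109 FPKM and the membrane glycoprotein gene GYPC 698 ± 104 FPKM. Among erythroid transcription factors, KLF1 led with 400 ± 90.0 FPKM (chromosome 19, 12995237 to 12998017), ahead of NFE2 with 366 ± 117 FPKM, TAL1 with 137 ± 26.1 FPKM and GFI1B with 133 ± 30.0 FPKM. GATA1 stood at 103 ± 22.1 FPKM.

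All 25 members of the erythroid membrane and cytoskeleton list and all 25 of the late erythroid maturation list reached 1 FPKM in each of the 6 libraries, as did 24 of the 25 erythroid transcription factors and 23 of the 25 heme and iron genes. Their list medians, as log2(FPKM + 0.1), were 6.52 ± 0.19 for the membrane list, 6.86 ± 0.32 for late maturation, 5.31 ± 0.50 for the transcription factors and 6.79 ± 0.14 for heme and iron (SD, n = 6). The transcription factor median was 4.58 when each gene was represented by its highest transcript. Lists of other blood lineages lay near the floor of the scale. The medians were -2.94 ± 0.19 for stem and early progenitor genes, -1.88 ± 0.17 for megakaryocyte and platelet genes, -2.22 ± 0.27 for neutrophil genes, -2.24 ± 0.38 for mast cell, basophil and eosinophil genes, -3.26 ± 0.06 for monocyte and macrophage genes and -3.27 ± 0.13 for lymphoid genes (SD, n = 6). CD34 itself was listed at 0 in 5 libraries and at 0.0138 FPKM in the other. KIT, the stem cell factor receptor gene, stood at 1.92 ± 0.960 FPKM.

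**Figure D1:**
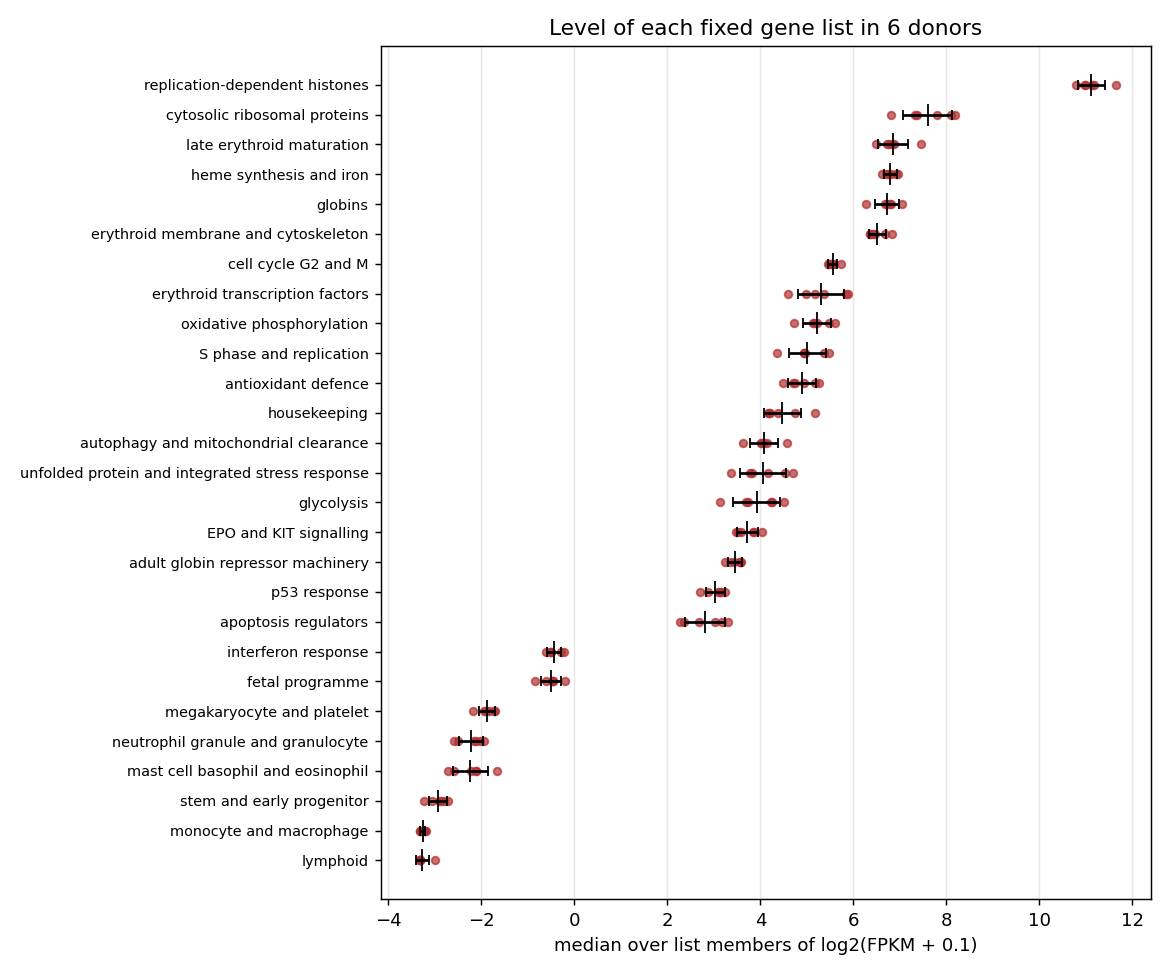
Median log2(FPKM + 0.1) of each of the 27 fixed gene lists on the horizontal axis; each point is 1 of 6 donors, the vertical tick is the mean and the bar 1 SD. The 4 erythroid lists sit between 5.31 and 6.86 on average, and the 6 lists of other lineages between -3.27 and -1.88.

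Each of the 4 erythroid lists was compared with each of the 6 other-lineage lists within libraries. All 24 differences were positive in 6 of 6 libraries, with adjusted p = 0.03125 by an exact two-sided sign-flip permutation test, which is also the smallest p that 6 libraries allow. The smallest mean difference was 7.18 ± 0.54 on the log2(FPKM + 0.1) scale, for the transcription factors against the megakaryocyte list, and the largest was 10.13 ± 0.37, for late maturation against the lymphoid list (SD, n = 6). The pseudocount and the silent members set these sizes, and the smallest difference was 5.11 at a pseudocount of 1 and 3.55, for the transcription factors against the monocyte list, when only members reaching 1 FPKM in some library were kept.

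A few genes of other lineages were expressed above that floor. PRG2, which encodes the major basic protein of eosinophil granules, stood at 23.6 ± 14.8 FPKM and CLC, the Charcot-Leyden crystal gene, at 5.79 ± 2.09 FPKM. SOCS2, a cytokine-induced feedback inhibitor placed in the progenitor list, stood at 14.3 ± 2.84 FPKM, and the platelet tubulin gene TUBB1 at 11.7 ± 1.82 FPKM. APOE stood at 4.04 ± 2.86 FPKM, LYZ at 2.17 ± 0.586 FPKM, GATA2 at 1.98 ± 0.603 FPKM, ITGA2B at 1.03 ± 0.650 FPKM and CCR7 at 1.04 ± 0.559 FPKM (SD, n = 6). MPO, the granule peroxidase gene of neutrophils, was at 0.745 ± 0.310 FPKM and CD14 at 0.173 ± 0.118 FPKM.

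The cells carried proliferation transcripts. All 20 members of the G2 and M list and all 20 of the S phase list reached 1 FPKM in each library, with list medians of 5.55 ± 0.09 and 5.01 ± 0.39 on the log2 scale (SD, n = 6). NUSAP1 stood at 135 ± 10.8 FPKM, UBE2C at 106 ± 12.9, CDK1 at 99.96 ± 7.33 and TOP2A at 84.3 ± 5.83, and in the S phase list PCNA stood at 153 ± 50.3 FPKM and MCM7 at 124 ± 33.9 FPKM. Replication-dependent histones were the most abundant list, with a median of 11.11 ± 0.29; HIST1H3B reached 6435 ± 901 FPKM and HIST1H4C 5617 ± 1750 FPKM. The ribosomal protein list had a median of 7.60 ± 0.52, and its highest member was RPL35A at 755 ± 309 FPKM. RPS29, a ribosomal protein gene outside that list, stood higher, at 2429 ± 1397 FPKM. The oxidative phosphorylation list had a median of 5.22 ± 0.31, led by ATP5B at 132 ± 21.6 FPKM.

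Among the remaining lists, antioxidant genes had a median of 4.89 ± 0.30, with PRDX2, which encodes a red cell peroxiredoxin, at 1289 ± 218 FPKM and CAT at 332 ± 62.6 FPKM. Autophagy and mitochondrial clearance genes had a median of 4.07 ± 0.30, with FBXO7 at 179 ± 22.1 FPKM and the mitophagy receptor gene BNIP3L at 113 ± 32.1 FPKM. Glycolysis genes had a median of 3.92 ± 0.51 and the EPO and KIT signalling list 3.72 ± 0.23, in which the kinase gene PIM1 stood at 360 ± 49.7 FPKM and EPOR at 68.9 ± 12.4 FPKM. Stress response genes had a median of 4.06 ± 0.50, with PPP1R15A at 223 ± 55.5 FPKM. DDIT3, a member of that list, was listed at 0 in all 6 libraries and overlaps another annotated gene. The p53 response list had a median of 3.03 ± 0.20, led by GDF15, an erythroblast-secreted factor, at 361 ± 186 FPKM. Apoptosis regulators had a median of 2.80 ± 0.43 and housekeeping genes 4.47 ± 0.40, with ACTB at 689 ± 118 FPKM. Interferon response genes had a median of -0.44 ± 0.15, and 8 of 20 reached 1 FPKM in all libraries, with RSAD2 at 51.6 ± 14.8 FPKM and IFI27 at 22.3 ± 6.92 FPKM.

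Short non-coding RNA and histone genes held a large part of the summed FPKM, which is not their share of reads, because FPKM divides by length. The 10 genes with the highest mean FPKM held 34.9% ± 2.35 of all FPKM (SD, n = 6), among them RMRP, RPPH1, SNORA63, HIST1H3B and HIST1H4C. RPPH1, the RNA component of RNase P, stood at 48660 ± 12906 FPKM. Genes with no transcript of 300 nt held 34.4% ± 3.97 of FPKM, and FPKM of such short transcripts is poorly determined because few fragments fit within them. With these genes left out of the ranking and the sum, the 10 highest held 27.6% ± 1.82.

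Globin transcripts were examined next, with the limit that globin messenger RNA was subtracted before sequencing. The values therefore describe what the subtraction left, and ratios between globin genes are not those of the cells. The gamma globin gene HBG2 was the most abundant globin at 3899 ± 1870 FPKM (hg19 chromosome 11, 5274421 to 5276011), followed by HBM at 1571 ± 664 FPKM, HBG1 at 509 ± 305, HBB at 436 ± 71.1 and HBD at 312 ± 49.6 FPKM (SD, n = 6). The theta globin gene HBQ1 stood at 44.2 ± 5.47 FPKM, and the alpha globin genes HBA2 and HBA1 at 36.8 ± 13.1 and 36.8 ± 6.97 FPKM. The embryonic gene HBE1 stood at 0.900 ± 0.359 FPKM, and HBZ lay between 0 and 2.76 FPKM. The gamma genes held 84.1% ± 5.05 of the FPKM of HBG1, HBG2, HBB and HBD, with a range of 76.9 to 92.3%. HBG2 exceeded HBG1 by 3.10 ± 1.56 log2 units in 6 of 6 libraries (adjusted p = 0.0375, exact two-sided sign-flip permutation test, 30 pairs), but both genes are near-identical copies, as are HBA1 and HBA2, and the assignment of reads between copies is uncertain. HBB exceeded HBE1 by 8.84 ± 0.52 log2 units in 6 of 6 libraries (adjusted p = 0.0375 by the same exact test). HBB was higher than HBD in 5 of 6 libraries, a difference of 0.48 ± 0.31 that did not pass (adjusted p = 0.069, same exact test).

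**Figure D2:**
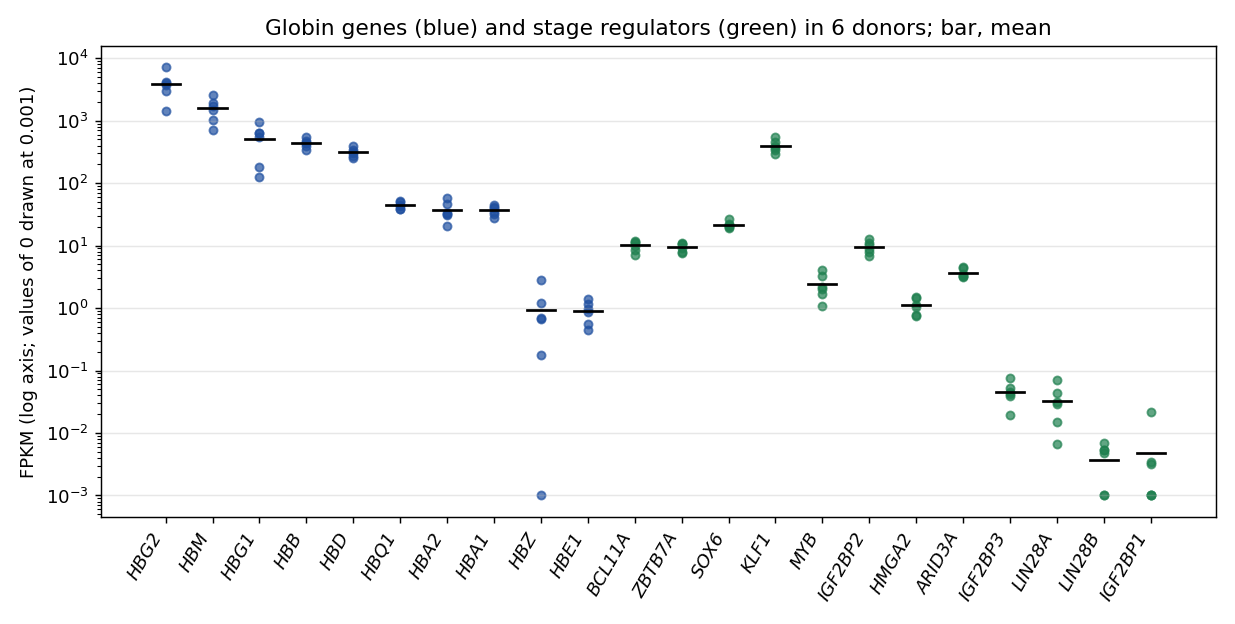
FPKM on a log axis for globin genes (blue) and for regulators of the fetal and adult stage (green); each point is 1 of 6 donors and the bar is the mean, with values of 0 drawn at 0.001. HBG2 averages 3899 FPKM, while LIN28B and IGF2BP1 reach at most 0.0218 FPKM in any donor.

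Regulators that separate fetal from adult erythroid cells showed a mixed pattern. The repressors of gamma globin were expressed, with BCL11A at 10.1 ± 1.88 FPKM, ZBTB7A at 9.46 ± 1.45, SOX6 at 21.4 ± 2.59 and MYB at 2.39 ± 1.11 FPKM (SD, n = 6), and 23 of 24 members of the repressor list reached 1 FPKM in all libraries, with a list median of 3.46 ± 0.15. The remaining member, EHMT2, was listed at 0 throughout and is also annotated on alternative haplotype sequences. The fetal programme list had a median of -0.51 ± 0.21. The fetal RNA-binding genes were near 0: LIN28A ranged from 0.00656 to 0.0703 FPKM, LIN28B from 0 to 0.00686, IGF2BP1 from 0 to 0.0218 and IGF2BP3 from 0.0195 to 0.0753 FPKM. IGF2BP2 stood at 9.61 ± 2.26, ARID3A at 3.67 ± 0.597, IGF2 at 5.10 ± 3.23, CDK6 at 2.96 ± 0.991, HIC2 at 2.76 ± 0.509 and HMGA2 at 1.10 ± 0.327 FPKM. PLAG1 stood at 0.652 ± 0.0862, PLAGL1 at 0.3998 ± 0.104 and NR6A1 at 0.358 ± 0.115 FPKM. H19 lay between 0 and 0.0509 FPKM, and MYCN and TRIM71 were listed at 0 in all libraries. BCL11A exceeded LIN28B by 6.59 ± 0.29 log2 units and IGF2BP2 exceeded IGF2BP3 by 6.04 ± 0.35, each in 6 of 6 libraries (adjusted p = 0.0375, exact sign-flip permutation test).

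Whether donors with a higher residual gamma globin share differed in these regulators was tested for 10 genes. None of the 10 correlations passed Benjamini-Hochberg adjustment, and at an unadjusted p under 0.05 there were 0 by Pearson's and 1 by Spearman's coefficient. The closest were KLF1 (r = 0.75, exact permutation p = 0.065, adjusted p = 0.38; rho = 0.89, p = 0.033, adjusted p = 0.33) and ARID3A (r = 0.78, exact permutation p = 0.076, adjusted p = 0.38; rho = 0.60, p = 0.24, adjusted p = 0.99). Without the 2 libraries farthest from the median, r was 0.76 for KLF1 and -0.80 for ARID3A. BCL11A had r = 0.16 (exact permutation p = 0.80) and rho = -0.03 (p = 1). With 6 libraries a moderate relation would not be detectable.

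Fixed pairs of related genes asked which member these cells used. Of 30 pairs, 25 passed the exact two-sided sign-flip permutation test after adjustment, each at adjusted p = 0.0375. ALAS2 exceeded the housekeeping isozyme ALAS1 by 8.31 ± 0.22 log2 units, GATA1 exceeded GATA2 by 5.66 ± 0.67, and KLF1 exceeded MYB by 7.42 ± 0.42 (SD, n = 6). The anti-apoptotic gene BCL2L1 stood at 178 ± 39.6 FPKM and exceeded BCL2 by 9.24 ± 0.92 and MCL1 by 2.08 ± 0.35. TFRC exceeded TFR2 by 4.15 ± 0.31, SLC25A37 exceeded SLC25A28 by 7.08 ± 0.27 and SLC4A1 exceeded SLC4A2 by 7.44 ± 0.26. SPTB exceeded SPTBN1 by 9.46 ± 1.02 and EPB41 exceeded EPB41L2 by 7.04 ± 0.18. GFI1B, NFE2 and TAL1 exceeded GFI1, NFE2L2 and LYL1 by 9.86 ± 0.51, 4.68 ± 0.50 and 1.07 ± 0.33. EPOR exceeded KIT by 5.21 ± 0.68 and HMGA1 exceeded HMGA2 by 5.18 ± 0.37. The ubiquitous pyruvate kinase gene PKM, at 0.516 ± 0.254 FPKM, was lower than the red cell gene PKLR by 5.03 in 6 of 6 libraries, a mean difference of -5.03 ± 0.20, and FTH1 was lower than FTL with a mean difference of -0.89 ± 0.42. Besides HBB and HBD, the pairs that did not pass were HBA2 and HBA1 (-0.05 ± 0.50), CA2 and CA1 (-0.26 ± 0.49), ZBTB7A and BCL11A (-0.08 ± 0.18) and HMOX2 and HMOX1 (-1.51 ± 1.03). Sizes against a gene below the pseudocount are limited by it.

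Use of annotated transcripts was compared for 24 genes with several RefSeq transcripts. The leading transcript exceeded the second in 21 of them (adjusted p = 0.036 each, exact two-sided sign-flip permutation test over 6 libraries); the leader was chosen on the same libraries, so the test is descriptive. BCL11A was assigned to NM_022893 alone, the longest of its 3 transcripts (5946 nt), in 6 of 6 libraries. BCL2L1 was assigned to NM_138578 alone, and in ALAS2 the transcript NM_000032 held 66.7% ± 1.13 and NM_001037967 33.3% ± 1.13 of the gene's FPKM (SD, n = 6). In EPB41, whose splicing changes during erythroid maturation, NM_001166007 held 75.4% ± 2.61 and NM_004437 24.6% ± 2.61. EPOR had 65.6% ± 4.31 in NM_000121 and 34.4% ± 4.31 in the non-coding NR_033663. ANK1 had 52.9% ± 9.10 in NM_020476 and 32.9% ± 5.64 in NM_020475. The 3 genes that did not pass were RUNX1, GATA2 and PKM, all with a mean below 2 FPKM. A transcript listed at 0 was not necessarily absent, since the assignment was estimated by the authors' tool from reads that isoforms share.

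The last comparison was of spread between donors. Of 8419 genes with a mean of at least 1 FPKM, 3064 had an SD under 0.2 on the scaled log2 scale and 184 had an SD above 1, with a median of 0.241. Both counts changed with the filter, the former also with the scaling and the latter with the pseudocount, as given in the closing section. Of those 184, 110 were listed at exactly 0 in at least 1 library, 59 had no transcript of 300 nt, and 62 had neither property. For 4757 genes with a single transcript, the SD between donors was 3.66 times (median) the SD implied by the deposited confidence interval, and it was the larger one in 98.3% of them. That interval covers the estimation within 1 library and leaves out library preparation and culture, so this ratio does not separate donors from them. Among genes of at least 300 nt and 10 FPKM, the widest spreads were those of HSPE1 (SD 4.41, at 0 in 4 libraries), TUBB (3.77, also annotated on alternative haplotype sequences, which limits what its value means), EXOSC9 (3.19, at 0 in 1 library), MRPL49 (2.93, at 0 in 1 library) and ABCC13 (2.08). TUBB2A (1.42), HIST1H4J (1.27), SCPEP1 (1.09), HBG1 (1.08), the fatty acid desaturase gene SCD (1.07), IFIT1B (1.04), TMSB10 (0.98) and the stress genes TRIB3 (0.98) and ATF5 (0.96) followed. The spread of HBG1 depends on the globin subtraction and on the uncertain assignment of reads between HBG1 and HBG2. The steadiest after scaling were SAR1A (0.015), RER1 (0.027), DDX24 (0.032), ARF5 (0.033), RAD23B (0.034), AP3D1 (0.037), RNF4 (0.042), AGPAT3 (0.043), USP22 (0.045) and PPP1R8 (0.046). Such a small SD means that a gene followed the scaling factor of the libraries, not that its deposited value was constant. Before scaling, SAR1A ranged from 9.48 to 14.0 FPKM and ARF5 from 26.0 to 39.7 FPKM.

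Gene lists were then placed among 10000 random lists of the same size and expression, drawn by permutation of genes. The spread of 7 of 23 lists was larger than that of random lists and the spread of 1 was smaller after adjustment. By this permutation of genes, glycolysis genes had a median SD of 0.58 against 0.25 (adjusted p = 0.0023), late maturation genes 0.41 against 0.26 (adjusted p = 0.0023), stress response genes 0.42 against 0.24 (adjusted p = 0.0061), p53 response genes 0.40 against 0.24 (adjusted p = 0.0092) and autophagy genes 0.40 against 0.24 (adjusted p = 0.011). Globins had 0.46 against 0.26 (adjusted permutation p = 0.039), and the mast cell, basophil and eosinophil list 0.65 against 0.24 with only 3 members measured above 1 FPKM (adjusted p = 0.029). Globin transcripts were subtracted before sequencing, so the globin spread includes any difference in subtraction between libraries. The globin repressor list had the smaller spread, 0.16 against 0.23 (adjusted permutation p = 0.049), and lost the call when any single library was left out (adjusted p 0.074 to 0.40) and under most other settings, as with FPKM as deposited (adjusted permutation p = 0.80). Leaving out 1 library at a time left between 2 and 6 lists past the threshold. Only glycolysis passed each time. Calls were lost without some library for autophagy (adjusted permutation p up to 0.16), globins (up to 0.11), p53 response (up to 0.15), the mast cell list (up to 0.059), stress response (0.054) and late maturation (0.29). With FPKM as deposited the late maturation, autophagy, globin and mast cell lists no longer passed (adjusted permutation p = 0.70, 0.79, 0.49 and 0.15). A filter at 5 FPKM removed the p53 and globin calls (adjusted permutation p = 0.25 and 0.083), and no filter that of the mast cell list (0.073).

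**Figure D3:**
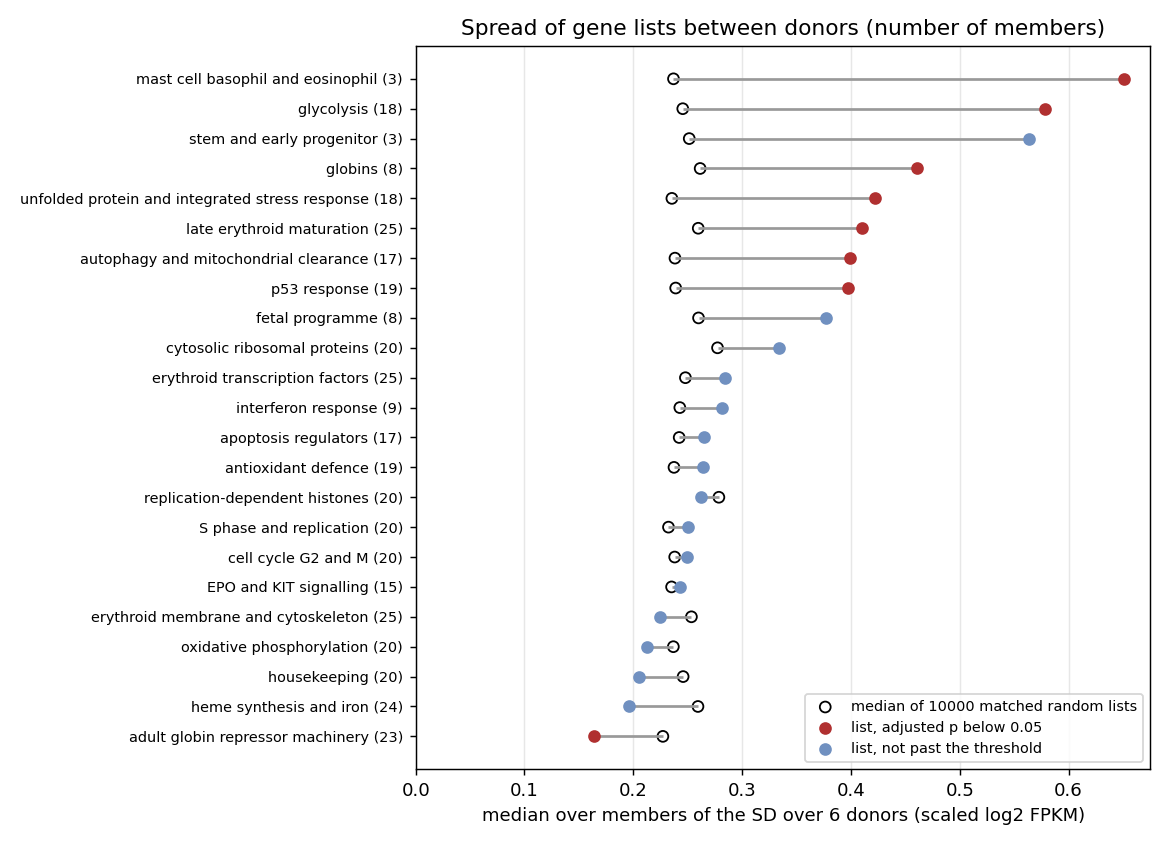
Median over list members of the SD between 6 donors (scaled log2 FPKM) for 23 gene lists, filled, against the median of 10000 random lists matched on expression, open; red marks an adjusted p below 0.05. Glycolysis lies at 0.58 against 0.25, and the globin repressor list at 0.16 against 0.23.

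Members of 13 of 23 lists moved together between donors more than random lists did. The mean pairwise r was 0.81 for ribosomal protein genes, 0.69 for G2 and M genes, 0.65 for histones, 0.60 for oxidative phosphorylation, 0.53 for stress response, 0.52 for late maturation, 0.49 for S phase and 0.44 for autophagy genes (adjusted permutation p = 0.00029 each). It was 0.25 for heme and iron, 0.24 for the membrane list, 0.25 for interferon response, 0.22 for p53 response and 0.21 for glycolysis (adjusted permutation p between 0.0023 and 0.032). With FPKM as deposited 5 lists passed, and the mean r of G2 and M (0.077), heme and iron (0.36) and the membrane list (0.33) lay below that of random lists. The calls of glycolysis and interferon response were lost after rescaling to a common sum (adjusted permutation p = 0.17 and 0.12), that of glycolysis also with a filter at 5 FPKM (0.095), and without some library those of p53 response (adjusted permutation p = 0.36), interferon response (up to 0.27), heme and iron and the membrane list (0.055 both). The oxidative phosphorylation list fell to a mean r of 0.017 (adjusted permutation p = 0.80) when a trend with GC content and length was removed, and the membrane list to 0.19 (adjusted permutation p = 0.12), an alternative chosen after the data were seen.

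Donors differed in how high the late maturation genes stood, and 12 relations of that score with other lists were tested. Heme and iron genes rose with it (r = 0.92, exact permutation p = 0.0042, adjusted p = 0.033; rho = 1.00, p = 0.0028, adjusted p = 0.033), with r = 0.91 without the 2 libraries farthest from the median. S phase genes fell with it (r = -0.95, exact permutation p = 0.0056, adjusted p = 0.033; rho = -0.94, p = 0.017, adjusted p = 0.10), with r = -0.85 without those 2 libraries, and 18 of the 20 members had a negative correlation. In the heme and iron list 21 of 24 members had a positive correlation and 3 a negative one, down to r = -0.93. Within the late maturation list 23 of 25 members rose with the score of the other members, while CA1 (r = -0.46) and CA2 (r = -0.61) fell. G2 and M genes had r = 0.54 (exact permutation p = 0.27, adjusted p = 0.41; rho = 0.77, p = 0.10), and autophagy genes r = 0.86 (exact permutation p = 0.031, adjusted p = 0.12; rho = 0.89, p = 0.033). Ribosomal protein genes had r = -0.69 (adjusted p = 0.26, exact permutation) and interferon response genes r = 0.81 (adjusted p = 0.25, exact permutation). The other 6 relations had adjusted p between 0.26 and 0.89 for Pearson's r and between 0.10 and 1 for Spearman's rho (exact permutation), the lowest being oxidative phosphorylation (r = -0.68, rho = -0.89). The megakaryocyte score among them rested on 2 members and the neutrophil score on 1, LYZ. The calls for heme and iron and for S phase were lost at a pseudocount of 1 (r = 0.89 and -0.95, adjusted p = 0.067 for both, exact permutation) and with a GC content and length trend removed (r = 0.88 and -0.97, adjusted p = 0.083 and 0.067, exact permutation), while r stayed about as large. Without 1 library r lay between 0.88 and 0.95 for heme and iron and between -0.975 and -0.92 for S phase, where 2 calls among 12 tests cannot pass with 5 libraries. The calls depended on the scaling of the libraries: with FPKM as deposited r was 0.42 for heme and iron and -0.36 for S phase (adjusted p = 0.69 for both, exact permutation), and after rescaling to a common sum 0.82 and -0.63 (adjusted p = 0.20 and 0.36). No batch or date was given in the labels, so no relation could be recomputed within batches.

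**Figure D4:**
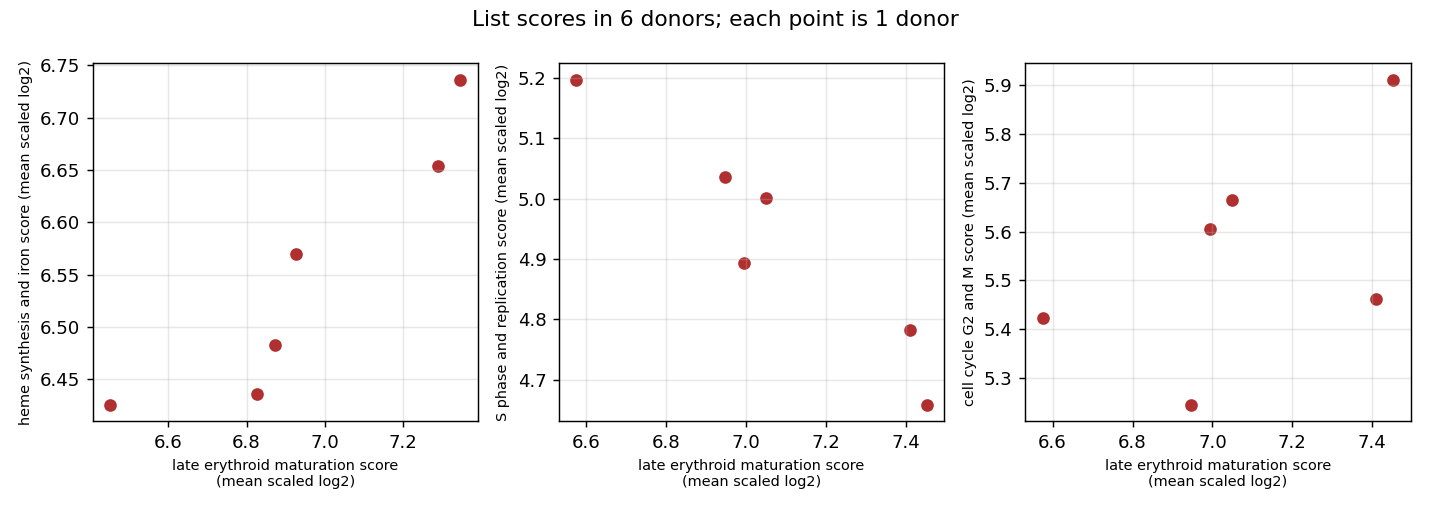
Scores of heme and iron, S phase and G2 and M genes (mean scaled log2 FPKM over members, vertical axes) against the late erythroid maturation score (same unit, horizontal axes); each point is 1 of 6 donors, without error bars. Heme and iron rise (r = 0.92) and S phase falls (r = -0.95) along the axis, while G2 and M have r = 0.54; with FPKM as deposited the first r values were 0.42 and -0.36.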

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

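In this part the overlap test for genes at exactly 0 was chosen only after the result was seen. Of 300 values tested for 1 library standing apart from the other 5, 22 did so (7.33%), where chance gives about 1 in 20, so most may be chance, and the odds ratio of 29.04 given below bears on only 1 of them, MRPL49. The rate of 1 in 20 holds for normally distributed values without ties. For the lymphoid median, FECH, GFI1B and CD34 the other 5 values were equal, so any departure stood apart. FPKM values in this test were not scaled between libraries. Summed FPKM ranged from 390676 to 712534, so some high values may follow their library.

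Each value below is that of 1 library, not necessarily the same library from value to value. Among list medians and pairs, these were a lymphoid median of -2.99 where the others were at the floor of -3.32, an HBA2 minus HBA1 difference of -1.03, a BCL2L1 minus MCL1 difference of 2.75 (others 1.73 to 2.102) and an FTH1 minus FTL difference of -0.0848 (others -1.22 to -0.88). Leading transcript shares of 89.3% for FECH and 87.6% for GFI1B stood below 100% in the others, and that of DMTN was 53.8% (others 59.1 to 61.1%). BNIP3L was high in 1 library, at 176 FPKM (others 90.1 to 116). RRM2, a ribonucleotide reductase gene, reached 147 FPKM (others 111 to 123). Histone genes each stood high in 1 library, HIST1H2AL at 4898, HIST1H2AM at 5291, HIST1H2BD at 3732, HIST1H3F at 3659 and HIST1H4J at 95.9 FPKM, as did the small RNAs RPPH1 at 73714 and SCARNA10 at 8747 FPKM. Low genes with 1 high library were CD34 at 0.0138, IGF2BP1 at 0.0218, ITGA2B at 2.28 and IPO8 at 3.32 FPKM. TUBB reached 43.7 FPKM where the others lay between 0.0270 and 13.9, a gene also annotated on alternative haplotype sequences, which limits what its value means, and MRPL49 was listed at 0 where the others lay between 12.5 and 19.8 FPKM.

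MRPL49 belongs to a wider pattern, 33 genes of at least 300 nt that reached 5 FPKM in some libraries and were listed at exactly 0 in others, HSPE1 and EXOSC9 among them. Of the 33, 0 had a transcript on an alternative haplotype, which argues against that source for these genes only. Among the 5382 other genes just 2 had one, so the odds ratio of 0 (95% interval 0 to 880, Fisher's exact test) cannot decide. EHMT2, annotated on such sequences, was listed at 0 throughout and so fell outside this set. The lowest nonzero value had a lower confidence bound above 0 in 97.0% of the 33. These genes were chosen for reaching 5 FPKM in some library, and only libraries above 0 entered that check. For genes at 0 in 5 libraries, such as PAM16, the value checked was the one that had selected them. The check therefore cannot decide whether levels were too low for the depth in the libraries at 0. Of the 33 genes, 30 (90.9%) overlap another annotated gene, against 25.6% of the other genes (odds ratio 29.04, 95% interval 9.01 to 149, Fisher's exact test). Assignment of reads to the other gene may therefore be the source of these zeros. No biological explanation was tested.

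The second pattern is the opposite movement of late maturation and S phase genes between donors. Removal of a GC content and length trend left r at -0.974, which argues against such a trend, although the adjusted p rose to 0.067 over the 12 relations. Library scaling may contribute and stays open. The condition set in advance for it, an r weaker than -0.5 under either other scaling, was met, as r was -0.364 with FPKM as deposited. After rescaling to a common sum, r stayed beyond that bound. That donors differed in how far their cultures had matured stays open: an added list of early erythroid genes had r = -0.677 with the late score (adjusted p = 0.18, exact permutation), which 6 libraries cannot settle, while an added list of other late genes had r = 0.95 (adjusted p = 0.021, exact permutation) and rho = 0.94 (adjusted p = 0.05, exact permutation), which does not pass. The early list includes growth genes such as MYC, CDK4 and NPM1. It also holds TFRC, a heme and iron list member with r = 0.57 to the late score. The early list is therefore not a measure of stage alone.

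The third pattern is the joint movement of ribosomal protein genes, with a mean pairwise r of 0.81. Removal of the GC content and length trend lowered it to 0.579, still above random lists (adjusted permutation p = 0.00038), so that trend does not account for the whole pattern. The 10 members with the fewest annotated pseudogenes (5 to 12 each) had 0.870, and the others (13 to 80 each) had 0.763. Every member had pseudogenes, and their number does not measure shared reads, so this split cannot decide whether such reads contribute. The share of short non-coding RNA in the library had r = 0.601 with the ribosomal protein score (exact permutation p = 0.20; rho = 0.54, p = 0.30) and r = 0.85 without the 2 farthest libraries. That met the size set in advance for this explanation, so short RNA may contribute, although the p does not exclude chance. Differences between donors or cultures in ribosomal protein expression stay open and were not tested.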

How the results depend on the processing

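The removal of GC content and length trends and of genes at exactly 0 were chosen after the data were seen. All 24 erythroid against other-lineage differences stayed positive under the alternatives run for them; the smallest was 3.55 with only members reaching 1 FPKM, 5.11 at a pseudocount of 1, 6.37 with list means and 6.51 with the highest transcript, and 7.07 to 7.36 when a library was left out; with 5 libraries the exact test cannot go below 0.0625. List medians moved by more than 1 SD in 40 cases and not in 95, mostly lists near the floor under another pseudocount, summary or filter; among expressed lists, the highest transcript gave 4.58 for transcription factors, 2.77 for p53 response and 3.46 for EPO and KIT signalling, and list means gave 6.30 for globins, 6.42 for heme and iron, 3.62 for the repressor list, 3.26 for p53 response, 3.25 for autophagy, 3.17 for EPO and KIT signalling and 5.13 for housekeeping genes. No paired analysis was possible because the samples form 1 group. With both genes at 1 FPKM or more, 13 of 17 pairs passed, the same 13 that passed among them before. The gamma globin share was 90.0% without HBD and 82.5 to 85.5% without 1 library. The 2 calls with the late maturation score became 0 at a pseudocount of 1, with FPKM as deposited, after rescaling to a common sum, with the GC and length trend removed, and without any 1 library (0 to 0), where r stayed between -0.975 and -0.92 for S phase and 0.88 and 0.95 for heme and iron and 5 libraries are too few for 2 calls among 12 tests to pass. Genes with an SD above 1 (184) numbered 113 at a pseudocount of 1, 78 with a filter of 5 FPKM, 411 with no filter and 74 without genes at 0, and 163 to 188 without 1 library. Genes with an SD under 0.2 (3064) numbered 1573 as deposited, 1802 after rescaling, 1982 with a filter of 5 FPKM and 12068 with no filter. List spread calls fell from 8 to between 2 and 6 without 1 library, the count being 2, 3 or 5 for 3 of the libraries. With FPKM as deposited the G2 and M spread was 0.14, now below random lists (adjusted permutation p = 0.0015); coordination calls fell from 13 to 5, and mean r lay below random lists for the membrane list (0.33), heme and iron (0.36) and G2 and M (0.077). Coordination of the stem list turned to 0.14 with no filter, and that of oxidative phosphorylation to 0.017 after trend removal. The 10 highest genes held 27.6% with short genes left out. The cause of these changes was not tested, except that filters change the genes counted. Depth in reads is unknown, which limits every statement on genes near 0.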

Other observations

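The tests in this part were set on lists written after the data were seen. Genes of amino acid supply moved between donors with the stress response. A list of 22 targets of ATF4, 20 of them above 1 FPKM on average, where ATF4 is the transcription factor of the integrated stress response, including the tRNA synthetase genes AARS and GARS and the mitochondrial folate genes SHMT2 and MTHFD2, followed the stress response score (r = 0.952, exact permutation p = 0.0042, adjusted p = 0.021; rho = 0.94, p = 0.017, adjusted p = 0.05, which does not pass; r = 0.96 without the 2 farthest libraries), and its members had a mean pairwise r of 0.44. The stress list itself holds 4 amino acid genes, ASNS, PSAT1, PHGDH and SLC7A11, and without them r was 0.92 (exact permutation p = 0.0069; rho = 0.94, p = 0.017). The members left still include ATF4 itself, so the 2 lists are not independent measures. Neither r was recomputed with FPKM as deposited, the setting that weakened the called relations to the late maturation score. The target list did not pass for a wider spread between donors than matched genes (median SD 0.28 against 0.24, adjusted permutation p = 0.28). A shared stress programme may link both lists, a hypothesis found and tested on the same 6 libraries.

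Cholesterol and fatty acid synthesis genes, 25 in all with FASN, INSIG1 and SCD among them, varied more between donors than matched genes, with a median SD of 0.356 against 0.22 for random lists (adjusted permutation p = 0.00067). A difference in lipid supply or in harvest between cultures is a candidate explanation that the labels cannot test. Proteasome genes showed the opposite, with a median SD of 0.13 against 0.23 (adjusted permutation p = 0.0005). Their relation to the late maturation score was r = -0.702 (exact permutation p = 0.11, adjusted p = 0.18), which 6 libraries leave open. The spreads of both lists and this relation were computed on scaled values only and were not recomputed with FPKM as deposited. In that setting the globin repressor list lost its smaller spread, so a small spread here may depend on the scaling.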
